A study of Mus musculus with 9 samples.

How the data were processed

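Gene expression was measured with an Illumina mouse expression array in 9 samples of mouse corneal epithelial cells, 3 per group, and the groups were taken from the sample labels. Per the labels, RNA was isolated with Trizol and an RNeasy column with DNase, and biotinylated cRNA was made with the Ambion MessageAmp kit for hybridization. The deposited table held 1 value per probe and array for 45281 probes. The deposited values were on a log2 scale, which was read from their range, with a lowest value of 6.32 and a highest of 15.13. Whether the authors corrected for background or transformed the values in another way is not given in the sources used here.

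The deposited arrays did not share a distribution. Their medians ran from 6.73 to 6.93, a range of 0.20, and their upper quartiles from 7.07 to 7.45. By a rule set for that case, the values were quantile normalized between arrays in limma. Folds were taken on this scale, which includes the background of each probe, so the folds of dim genes are understated. The number of arrays limits the precision, and an array has no count depth to report. Nothing in the labels says whether the 3 samples of a group came from separate animals, so the p-values measure only the spread between these samples.

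Each probe was named from the annotation of the array. A single gene symbol was found for 34885 probes, of which 34807 were updated through their Entrez identifier, 11 were named through an accession and 67 kept the platform's symbol. The other 10396 probes had several symbols or none and were tested apart from the genes. For a gene with several probes, the probe with the highest mean over the 9 arrays was used, which left 19053 genes. No position on the genome is given, because the genome build behind the annotation of the array is not stated.

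A background limit was set for each array after the data had been seen. It was the 95th percentile of 1506 probes for olfactory and vomeronasal receptors, which are not known to be expressed in corneal epithelium. Where all 3 arrays of the lower group lay under their limits, the fold is given as at least the ratio of the higher mean to the limit. The share of all probes above the limit parted the arrays at its widest gap into a dimmer set of 4 and a brighter set of 5.

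The 3 groups were fitted together in limma 3.58.1 under R 4.3.3, and 3 comparisons were drawn from the fit: PA against control, flagellin + PA against control, and flagellin + PA against PA. A change was called at an adjusted p below 0.05, by the Benjamini-Hochberg method over all genes of a comparison. Every adjusted p of a gene is from limma, every SE is the standard error of the log2 difference, and n was 3 arrays per group. The figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

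The genes named were chosen by a rule. It took, per comparison, the 10 largest rises and the 10 largest falls among called genes whose values did not overlap between the groups, leaving out symbols of unnamed transcripts. It also took up to 4 called members with the smallest p from each of 28 gene lists, or up to 2 members as values where none was called, and S100a8, S100a9, Cxcl10, Camp, Krt12 and Tlr5. The values of the groups did not overlap for any gene that is named with a call, so all 3 arrays of the higher group lay above all 3 of the lower group; chance gives this for 10% of genes. A gene outside the rule is said to have been chosen after its values were seen.

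The 28 lists were written from textbook knowledge. They covered the epithelial response (chemokines, cytokines, antimicrobial proteins, interferon-stimulated genes, NF-kB feedback and negative regulators, microbial receptors and adaptors, matrix proteases and wound response, eicosanoid and lipid mediator genes, complement and acute phase), the epithelium itself (cornified envelope and stress keratins, corneal epithelial identity, junctions and surface mucins), cell state (hypoxia and glycolysis, oxidative phosphorylation, cell cycle, immediate early and heat shock genes, antioxidant and metallothionein genes, cell death genes, circadian clock, cytosolic ribosomal proteins), other cells (markers of neutrophils, of macrophages and dendritic cells, of lymphocytes and NK cells, of keratocytes and fibroblasts, of conjunctival and goblet cells, of vessels, lens or retina, and of erythroid cells) and sex-linked genes. Each was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 28 lists of a comparison. An estimated correlation was the alternative, and at that setting 1 list call of 22 held, that of the cornified envelope list in PA against control. The members called were also counted with p-values adjusted over the list alone. The median, the mean and the test of a list differed in sign for 8, 12 and 5 lists in the 3 comparisons, none of them called.

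The groups, comparisons, tests, lists, naming rule and a first set of other settings were fixed before the data were examined. Those settings were the values as deposited, a common median per array, a floor at the 25th percentile, the brighter part of the genes, all probes of a gene averaged, a fit of the compared groups only, the replicate number as a block, limma with a trend and robust spread, array weights, an estimated correlation for the lists, and each array left out in turn. After seeing the data, 4 alternatives were added: a normexp background correction, controls 1 and 2 left out, PA 1 and flagellin + PA 3 left out, and the brightness set as a block. In that last fit, PA against control rests on PA 1 and the 3 controls, and flagellin + PA against PA rests on PA 2 and PA 3 and the 3 flagellin + PA arrays. For the latter comparison the block, the values within the brighter set and the fit without PA 1 are therefore one fit. Flagellin + PA and control then share no set and are linked only through PA.

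Overlaps between comparisons were set beside the number that independent draws give and beside simulated data without effects of the same sizes, since both comparisons use the PA arrays; those of the blocked fit were simulated with its spread, a test added after seeing the data. The calling was tested on simulated data of 19053 genes: of 100 genes shifted by 1 on the log2 scale limma called 81, of 100 shifted by 2 it called 99, and 11 calls were false. The shifted genes were drawn from brighter genes only. The simulated noise was independent between genes and arrays and held no difference between brightness sets. These figures therefore do not cover dim genes or the influence of single arrays.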

Results

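The series profiled RNA from the epithelial cells of the mouse cornea under 3 conditions, each with 3 arrays. Control cells were scraped from corneas without infection. PA cells were taken 6 h after infection with Pseudomonas aeruginosa, a Gram-negative bacterium that infects the cornea. Flagellin + PA cells were pretreated for 24 h with flagellin, the protein of the bacterial flagellum and the ligand of the receptor Tlr5, and then infected for 6 h. No group received flagellin alone, so what flagellin does by itself and what it does to the response to infection are not separable. The series title names the reprogramming of the response to infection by flagellin as the subject.

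Control and infected arrays separated along the first principal component of the normalized values, which held 49% of the variance over 4817 genes. The second held 22.1% and set PA 1 at -28.65 apart from the other 8 arrays, at -4.92 to 15.55. By the share of probes above background the arrays fell into 2 sets, found after the data were seen: the 3 controls and PA 1 at 33.5% to 36.1%, and PA 2, PA 3 and the 3 flagellin + PA arrays at 38.7% to 40.6%. Because the sets partly follow the groups, values with the set as a block stand beside the comparisons. In the blocked fit PA against control rests on PA 1 alone and the 3 controls, so that PA 1 is assumed to vary like the arrays of the other groups. Flagellin + PA against PA is then the same fit as leaving out PA 1. Flagellin + PA against control is the sum of both differences, so whatever sets PA 1 apart from PA 2 and PA 3 is carried into it.

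**Figure D1:**
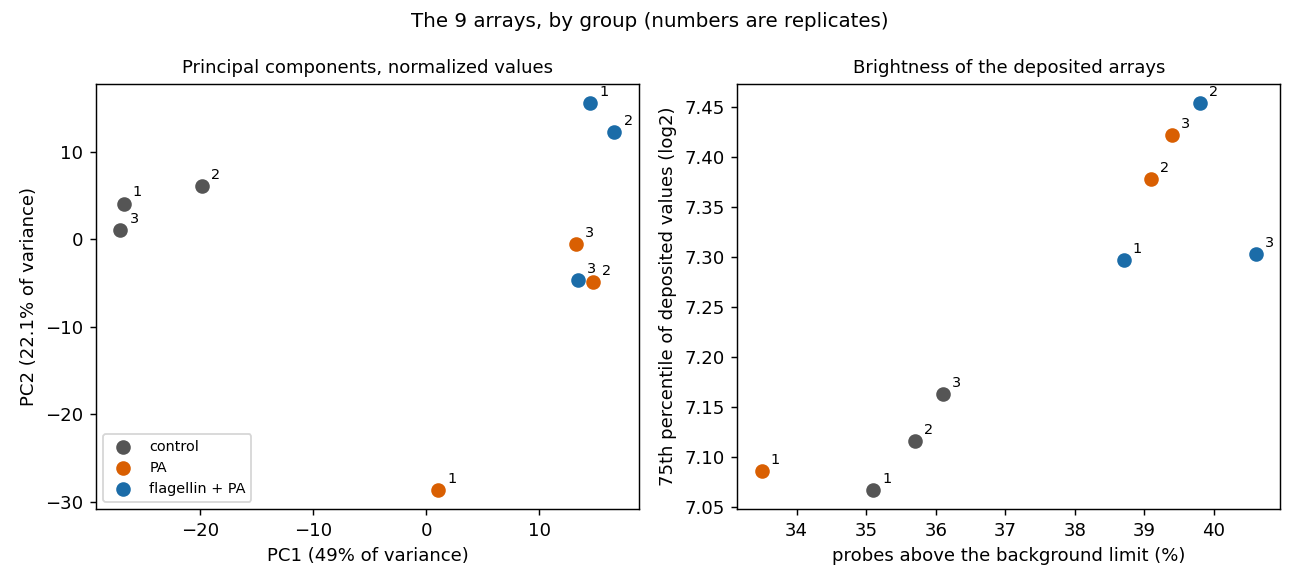
Left, each array (dot, numbered by replicate) on the first and second principal components of the normalized log2 values, colored by group; right, the upper quartile of its deposited log2 values against the share of probes above the background limit. PA 1 lies at -28.65 on the second component and, at 33.5% of probes, among the controls in brightness, while the other 5 infected arrays lie at 38.7% to 40.6%.

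The comparison of PA with control asks what 6 h of infection changed in these cells. The calcium-binding proteins S100a8 and S100a9, which together form the antimicrobial calprotectin, were among the largest rises. S100a9 (probe ILMN_2803674) rose from 8.13 ± 0.13 to 12.67 ± 0.09 (log2 intensity, SD, n = 3), a log2 change of 4.54 ± 0.16 (SE, adjusted p = 2.49e-05). S100a8 (ILMN_2710905), at background in the controls, rose at least 34.3-fold (log2 change 5.14 ± 0.44, adjusted p = 0.00113). The stress keratin Krt16 rose by 4.53 ± 0.35 (adjusted p = 0.000805), to 14.53. The collagenase Mmp13 rose by 5.04 ± 0.80 (adjusted p = 0.00753), and the cysteine protease inhibitor Csta3 at least 26.3-fold (adjusted p = 0.00175). The anion exchanger Slc26a4 rose by 3.10 ± 0.56 (adjusted p = 0.0134), a call that was lost without control 1 or 3 (adjusted p of up to 0.0592).

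Cornification genes, which build the tough outer layer of stratified epithelia, moved as a group: 14 of 47 measured members rose (18 adjusted over the list alone), with a median log2 change of 0.31 (camera adjusted p = 4.88e-12, and adjusted p = 0.0282 with an estimated correlation). Beside Krt16 they included the small proline-rich protein Sprr1a, up by 3.28 ± 0.40 (adjusted p = 0.00271), cornifelin (Cnfn), up by 2.74 ± 0.19 (adjusted p = 0.000766), and the late cornified envelope gene Lce3c, up by 1.89 ± 0.24 (adjusted p = 0.00358). With the brightness set as a block, 10 members were called and the estimated-correlation value became 0.0662. Another small proline-rich gene, Sprr2d, rose by 3.26 ± 0.44 (adjusted p = 0.00429). The corneal keratin Krt12 stood near the top of the scale at 14.80 in controls and 14.50 in PA (adjusted p = 0.0766). The list of corneal epithelial identity, with 5 of 34 members called higher, did not pass as a list (adjusted p = 0.051). Its called members included Sfn, an epithelial 14-3-3 protein, up by 1.64 ± 0.16 (adjusted p = 0.00141), and the transcription factor Grhl3, up by 0.89 ± 0.10 (adjusted p = 0.00239).

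Inflammatory genes rose in smaller numbers in the fit without the block, a ranking that was not tested. With the block, which takes PA 1 alone, the median of NF-kB feedback (0.47) was above that of cornification (0.17). The blocked medians of chemokines (0.04), cytokines (0.11) and antimicrobial proteins (0.05) were below that of cornification. By the share of members called, the blocked fit instead set NF-kB feedback, cytokines and chemokines above cornification. Antimicrobial proteins stayed below cornification by that share too. The order of the lists thus depended on the fit and on the measure. Of 26 chemokines 4 were higher, among them the neutrophil attractants Cxcl2, up at least 4.31-fold (adjusted p = 0.0014), and Cxcl1, up by 3.14 ± 0.67 (adjusted p = 0.0234), and the scavenger chemokine Cxcl16, up by 1.54 ± 0.22 (adjusted p = 0.00525); the list as a whole gave an adjusted p of 0.0643, and with the block it passed (adjusted p = 0.00226, and adjusted p = 0.133 with an estimated correlation). The Cxcl1 call was lost without control 1, 2 or 3 or PA 2, with an adjusted p of up to 0.0807 without control 1. Of 37 cytokines 4 rose, as many as adjusted over the list alone (adjusted p = 0.000171, and adjusted p = 0.202 with an estimated correlation), including the interleukin-1 receptor antagonist Il1rn, up by 0.89 ± 0.13 (adjusted p = 0.00583), and Il1f8, an IL-36 cytokine, up by 0.61 ± 0.09 (adjusted p = 0.00481). Of 40 antimicrobial proteins 5 rose, and 7 adjusted over the list alone (adjusted p = 0.00633, and adjusted p = 0.332 with an estimated correlation); S100a7a, psoriasin, was up by 1.56 ± 0.18 (adjusted p = 0.00241). Camp stayed at background in all groups, with mean log2 intensities of 6.64 to 6.71. Cxcl10, at 6.99 in PA and 6.84 in control, was not called (adjusted p = 0.671) and was at background in all arrays but PA 1, at 7.39, beside 6.80 and 6.77 in PA 2 and PA 3. The blocked fit, which takes PA 1 alone, gave a log2 change of 0.55 in PA and in flagellin + PA against control, the latter carried over from PA 1. The flagellin + PA arrays themselves stood at 6.78, 6.73 and 6.83, and the controls at 6.90, 6.81 and 6.81. Of 40 genes of NF-kB feedback 8 rose, and 11 rose and 2 fell adjusted over the list alone (adjusted p = 1.43e-05, and adjusted p = 0.449 with an estimated correlation). Their median was 0.16, against 0.47 with the block. The endonuclease Zc3h12a, which degrades inflammatory mRNAs, rose by 1.60 ± 0.17 (adjusted p = 0.00174), and Socs3, an inhibitor of cytokine signaling, by 3.06 ± 0.68 (adjusted p = 0.0285). The Socs3 call was lost without any 1 of 5 arrays, with an adjusted p of 0.108 without control 1, and in the values as deposited (log2 change 3.17, adjusted p = 0.0569). Within the group PA 1 had the highest Cxcl1 level, 12.29 against 10.36 and 9.20 in PA 2 and PA 3, and the median of the NF-kB list over the control mean was 0.47 in PA 1 against 0.09 and 0.16.

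Tissue repair and metabolic genes rose beside them. Of 44 genes of matrix proteases and wound response 9 rose and 2 fell, and 14 rose and 3 fell adjusted over the list alone (adjusted p = 2.89e-05, and adjusted p = 0.42 with an estimated correlation). They included the metalloproteinase inhibitor Timp1, up at least 3.89-fold (adjusted p = 0.00113), and stromelysin-1 (Mmp3), up at least 2.44-fold (adjusted p = 0.00345). The median of the list over the control mean was 0.49 in PA 1 and 0.13 and 0.14 in PA 2 and PA 3. Its median log2 change was 0.20, and 0.49 with the block, which takes PA 1 alone. Of 33 genes of hypoxia and glycolysis 10 rose, and 13 rose and 1 fell adjusted over the list alone, with a median of 0.26 (adjusted p = 1.71e-07, and adjusted p = 0.202 with an estimated correlation). The hypoxia-responsive gene Ndrg1 rose by 1.77 ± 0.19 (adjusted p = 0.00183) and the transferrin receptor Tfrc by 1.40 ± 0.17 (adjusted p = 0.00315). With the block, 5 members of this list were called higher and 2 lower. Metallothionein Mt2 rose by 2.30 ± 0.18 (adjusted p = 0.000805) and the protease inhibitor Serpina3n at least 6.33-fold (adjusted p = 0.000805). Of 31 cell death genes 4 rose and 2 fell, and 4 and 3 adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.202 with an estimated correlation). Of 63 interferon-stimulated genes 6 rose, and 7 rose and 1 fell adjusted over the list alone, with a median of 0.22 (adjusted p = 6.6e-06, and adjusted p = 0.449 with an estimated correlation). With the block, which takes PA 1 alone, the median was 0.41. The number called was 2 without control 3 and 9 without flagellin + PA 3. Ifitm3, an antiviral membrane protein, was up by 2.08 ± 0.29 (adjusted p = 0.00484).

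The genes that fell furthest had smaller changes. Sphkap, an anchoring protein for protein kinase A, fell by 2.09 ± 0.23 (adjusted p = 0.00212), the receptor tyrosine kinase Kit by 1.75 ± 0.27 (adjusted p = 0.00653), the corepressor Hr by 1.62 ± 0.16 (adjusted p = 0.00142) and Lrig3 by 1.49 ± 0.08 (adjusted p = 0.000143). Igfbp5, Cdo1, Sema5a, Palmd and Gask1b had log2 changes of -1.61, -1.54, -1.52, -1.49 and -1.46, and Sesn1 had -1.95. Of these, Palmd was no longer called with the block (log2 change -1.22, adjusted p = 0.0763) and Sesn1 without control 3 (adjusted p = 0.0521), and both calls were lost as deposited (adjusted p = 0.0731 and 0.126) and with a common median (adjusted p = 0.0601 and 0.107). Of the 34 falls that the naming rule took in this comparison 8 kept their call as deposited, 10 with a common median, 18 with the block and 20 without each array in turn; of its 53 rises 40, 38, 43 and 33 did. Tlr5, the receptor for flagellin, was lower in both infected groups: it went from 8.81 ± 0.08 in controls to 7.99 ± 0.18 in PA (SD, n = 3), a log2 change of -0.83 ± 0.12 (adjusted p = 0.00547). The Tlr5 call was lost in the values as deposited (log2 change -0.58, adjusted p = 0.0676) and with a common median (adjusted p = 0.0653). The list of microbial receptors and adaptors that holds Tlr5 had 3 of 36 members lower and did not pass (adjusted p = 0.51).

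In all, 416 genes were higher and 1248 lower in PA than in control, of which 137 rises and 95 falls were at least 2-fold; 3991 genes had an unadjusted p below 0.05. The balance between rises and falls depended on the scaling: 75% of calls were falls after quantile normalization, 28.2% in the values as deposited (199 higher, 78 lower) and 50.5% with a common median (145 higher, 148 lower). With the brightness set as a block 661 genes were higher and 936 lower, and 239 of the rises and 611 of the falls were the same genes. Without control 1 the counts were 167 higher and 596 lower, and without PA 1 they were 1109 and 1861.

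The comparison of flagellin + PA with control asks what pretreatment and infection changed together. Here interferon-stimulated genes, which block viruses and mark a response to interferons, were the largest group: 41 of 63 rose (49 adjusted over the list alone), with a median log2 change of 1.04 (adjusted p = 7.51e-33, and adjusted p = 0.101 with an estimated correlation). Ifi27l2a rose from 7.27 ± 0.29 to 10.85 ± 0.32 (SD, n = 3), a change of 3.58 ± 0.20 (SE, adjusted p = 0.00019). Rsad2, which encodes viperin, rose by 3.61 ± 0.58 (adjusted p = 0.0074), Ifitm3 by 3.50 ± 0.29 (adjusted p = 0.000795), the ISG15 protease Usp18 by 3.37 ± 0.42 (adjusted p = 0.00274) and the galectin ligand Lgals3bp by 3.18 ± 0.19 (adjusted p = 0.00023). The median of the list over the control mean was 1.27, 1.06 and 0.91 in the 3 flagellin + PA arrays and 0.41, 0.06 and 0.18 in the 3 PA arrays.

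Antimicrobial and cornification genes were again high. Of 40 antimicrobial proteins 11 rose, and 13 adjusted over the list alone (adjusted p = 7.68e-07, and adjusted p = 0.101 with an estimated correlation). S100a8 rose at least 119-fold (log2 change 6.94 ± 0.44, adjusted p = 0.000295), S100a9 by 5.64 ± 0.16 (adjusted p = 4.17e-06), the chitinase-like protein Chil1 at least 11.7-fold (adjusted p = 0.00659) and the peptidoglycan recognition protein Pglyrp4 by 1.94 ± 0.21 (adjusted p = 0.00163). Of 47 cornification genes 12 rose, and 17 rose and 1 fell adjusted over the list alone (adjusted p = 1.2e-08, and adjusted p = 0.0719 with an estimated correlation); with the block 6 were called. Krt16 was up by 4.40 ± 0.35 (adjusted p = 0.000703), Sprr2d by 3.99 ± 0.44 (adjusted p = 0.00175), Cnfn by 3.00 ± 0.19 (adjusted p = 0.000298) and Sprr2f by 2.97 ± 0.32 (adjusted p = 0.0016). Csta3 rose at least 9.55-fold (adjusted p = 0.00588). Krt12 stood at 14.47 against 14.80 in controls (adjusted p = 0.0533).

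Further lists passed against control. Of 42 cell cycle genes 8 rose and 1 fell, and 11 and 1 adjusted over the list alone (adjusted p = 1.95e-06, and adjusted p = 0.101 with an estimated correlation), led by thymidine kinase Tk1, up by 0.80 ± 0.09 (adjusted p = 0.00214). With the block the list passed (adjusted p = 0.00018, and adjusted p = 0.148 with an estimated correlation) with none of its members called; Tk1 kept its size at 0.80 (adjusted p = 0.0525). Of 33 genes of hypoxia and glycolysis 6 rose, and 14 adjusted over the list alone (adjusted p = 6.84e-07, and adjusted p = 0.156 with an estimated correlation); with the block this list no longer passed (adjusted p = 0.15), and Pkm, a pyruvate kinase up by 1.11 ± 0.13 (adjusted p = 0.00225), went to 0.91 (adjusted p = 0.0766). Of 37 cytokines 2 rose, as many as adjusted over the list alone (adjusted p = 0.0409, and adjusted p = 0.316 with an estimated correlation). The list did not pass in the values as deposited (adjusted p = 0.137) or with a common median (adjusted p = 0.152). Its median was 0.03, and 0.13 with the block, which runs through PA 1. The glutathione transferases Gstm1 and Gstm2 fell by 0.97 ± 0.08 (adjusted p = 0.000795) and 1.29 ± 0.15 (adjusted p = 0.00199).

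Among the largest falls were the stress granule protein G3bp1, down with a log2 change of -1.77 ± 0.12 (adjusted p = 0.000441), the G protein subunit Gng13, at -1.53 ± 0.08 (adjusted p = 0.00019), Ooep at -1.59, the ganglioside synthase St3gal5 at -1.48 and Rasgrf1 at -1.46. The calls of Piezo2 (-1.78), Kit (-1.67), Cyp4a12b (-1.58), Krt78 (-1.48) and Igfbp5 (-1.45) were lost with the block, at adjusted p-values of 0.107, 0.26, 0.438, 0.0678 and 0.307 and log2 changes of -0.73, -0.84, -1.20, -1.56 and -0.60. Tlr5 was at 8.00 ± 0.21 (SD, n = 3), a log2 change of -0.81 ± 0.12 from control (SE, adjusted p = 0.00561). That call was lost as deposited (adjusted p = 0.131), with a common median (adjusted p = 0.132) and with the block (log2 change -0.50, adjusted p = 0.205).

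Against control, 536 genes were higher and 1239 lower after flagellin and infection, with 167 rises and 77 falls of at least 2-fold and 4325 genes at an unadjusted p below 0.05. In the values as deposited 425 were higher and 53 lower, and with a common median 311 and 85. With the block 332 were higher and 371 lower, of which 130 and 196 were the same genes; all 6 arrays of this comparison differ in brightness set by group, so that this fit compares them only through PA. Of the 60 rises and 36 falls that the naming rule took, 46 and 11 kept their call as deposited, 40 and 13 with a common median, 28 and 11 with the block, and 34 and 26 without each array in turn. Without control 1 the counts were 240 higher and 629 lower, and without PA 1 they were 1146 and 1927. PA and flagellin + PA shared 177 rises and 809 falls against control, where simulated data without effects and with shared control arrays gave 113.2 and 384.6 on average. Those simulations held no difference in brightness or in sex-linked transcripts, which both partly follow the groups. Every gene counted in them was noise, unlike the calls. The excess therefore does not separate a shared response to infection from such differences between controls and infected arrays.

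**Figure D2:**
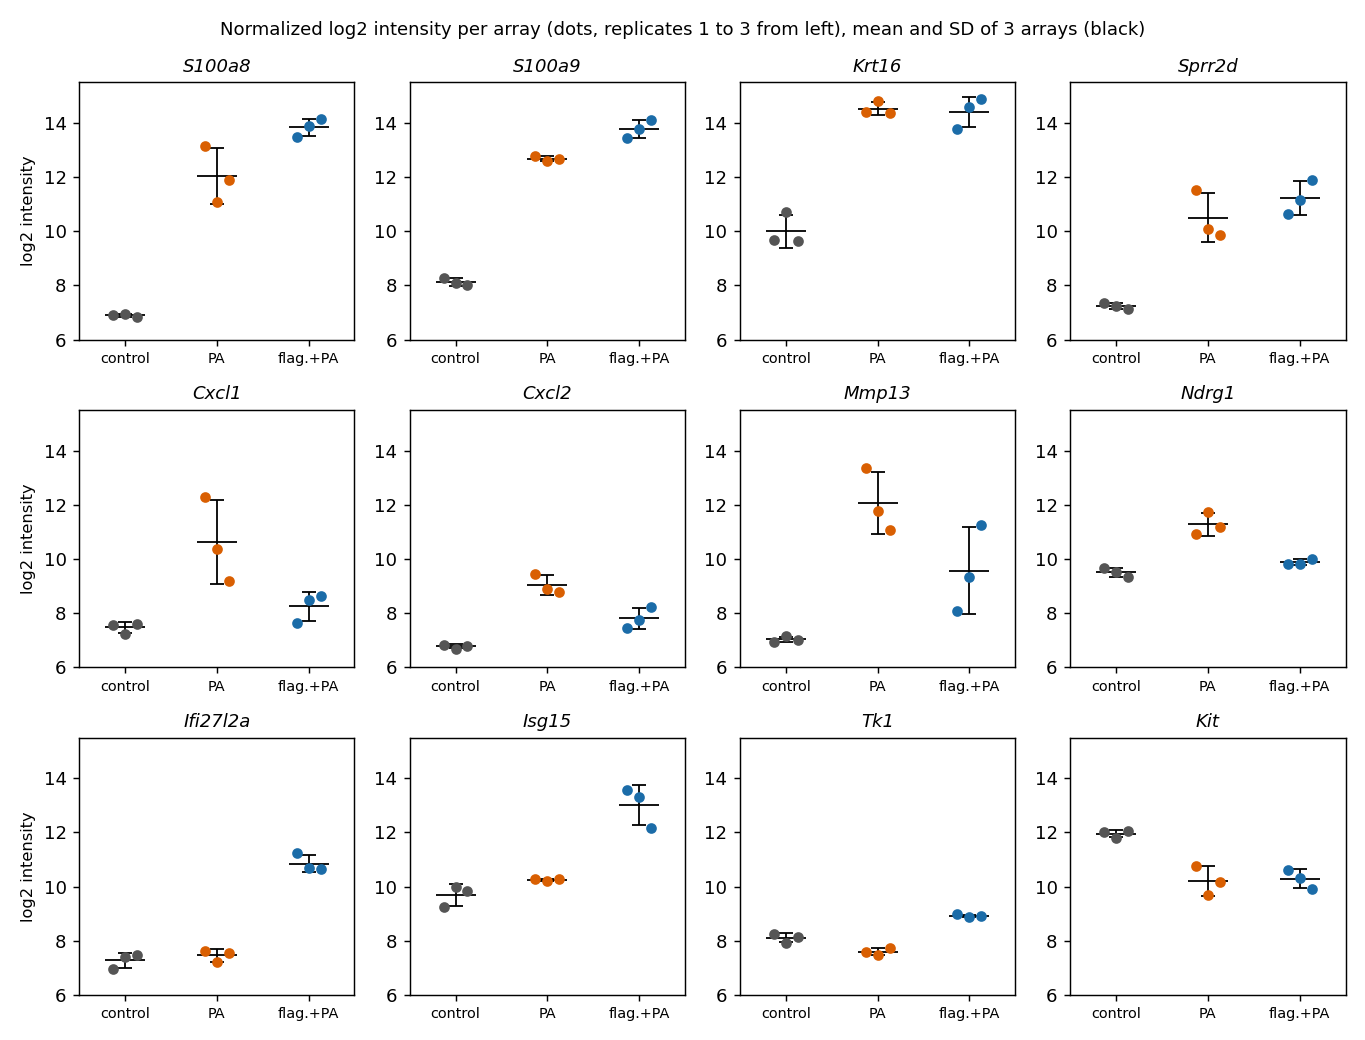
Normalized log2 intensity of 12 genes in each array (dots, 3 per group), with the mean and SD of the group in black; all panels share a scale that starts at 6. S100a8 went from 6.90 in controls to 12.04 in PA and 13.83 in flagellin + PA, Cxcl2 was highest in PA, and Ifi27l2a and Isg15 were high in flagellin + PA.

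The comparison of flagellin + PA with PA asks what pretreatment changed in infected cells. Interferon-stimulated genes were the main difference: 22 of 63 were higher after pretreatment (44 adjusted over the list alone), with a median log2 difference of 0.81 (adjusted p = 1.31e-35, and adjusted p = 0.103 with an estimated correlation). Ifi27l2a was higher by 3.39 ± 0.20 (adjusted p = 0.0018), Lgals3bp by 2.84 ± 0.19 (adjusted p = 0.00225), and the apolipoprotein L genes Apol9a and Apol9b by 2.53 ± 0.23 and 2.46 ± 0.22 (adjusted p = 0.00428 for both). The interferon-induced GTPase Gvin1 was higher by 2.52 ± 0.19 and Csprs by 2.31 ± 0.18 (adjusted p = 0.00313 for both). The ubiquitin-like protein Isg15 went from 10.25 ± 0.04 in PA to 13.01 ± 0.75 (SD, n = 3; log2 difference 2.76, adjusted p = 0.0155), beside Oas1g at 2.42, Gbp3 at 2.29 and Igtp at 2.44. Without PA 2, flagellin + PA 1 or flagellin + PA 2 these 4 calls were lost, with adjusted p-values of up to 0.0671 for Isg15, 0.0776 for Oas1g, 0.0792 for Gbp3 and 0.141 for Igtp; the Igtp call was also lost without any control or PA 3. Without PA 2 only 6 members were called, and without PA 1 there were 36. Within the brighter set, which is the fit without PA 1 and no separate check, these 36 had a median of 0.84 (adjusted p = 7.24e-47, and adjusted p = 0.0761 with an estimated correlation). Macrophage and dendritic cell markers also passed there, with 3 of 35 higher and a median of 0.04 (adjusted p = 0.0362, and adjusted p = 0.392 with an estimated correlation). With all arrays 1 of these markers, the protease Ctss, was higher than in PA (adjusted p = 0.0395), and 2 adjusted over the list alone. Ctss was at background in all 3 PA arrays, so its log2 difference of 0.40 is understated. Ctss, Mpeg1 and Plac8 were higher than in control, by 0.38, 0.25 and 0.87. The call of Ctss against PA was lost as deposited (adjusted p = 0.095) and without any 1 of 7 arrays (adjusted p of up to 0.149), and none of the 3 calls against control held with the block (adjusted p = 0.139, 0.138 and 0.936). The other probe of Mpeg1 differed by -0.13.

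Cell cycle genes were higher after pretreatment, with 3 of 42 called (14 adjusted over the list alone) and a median difference of 0.36 (adjusted p = 8.32e-14, and adjusted p = 0.0556 with an estimated correlation). In PA against control 3 members were lower and 0 higher, with a median of -0.12, and the list did not pass (camera adjusted p = 0.293). For Tk1 part of the difference is a lower level in PA: it stood at 8.26, 7.93 and 8.14 in controls and at 7.59, 7.46 and 7.73 in PA. Tk1 was higher by 1.32 ± 0.09 (adjusted p = 0.00296). The spindle protein Nusap1 was higher by 1.01 ± 0.16 (adjusted p = 0.027) and the replication helicase subunit Mcm5 by 0.86 ± 0.11 (adjusted p = 0.0188). The calls of Nusap1 and Mcm5 were lost as deposited (adjusted p = 0.0664 and 0.173), and without flagellin + PA 1 (adjusted p = 0.107 and 0.0846). Of 40 antimicrobial proteins 2 were higher, and 5 adjusted over the list alone (adjusted p = 9.21e-05, and adjusted p = 0.2 with an estimated correlation): S100a9 by 1.10 ± 0.16 (adjusted p = 0.0246) and the beta-defensin Defb14 by 1.5 ± 0.23 (adjusted p = 0.0269). Both calls were lost without PA 2 (adjusted p = 0.101 and 0.113), and that of S100a9 also as deposited (log2 difference 1.34, adjusted p = 0.0633) and with a common median (adjusted p = 0.0512). S100a8 differed by 1.80 ± 0.44, which did not pass (adjusted p = 0.111), and by 2.35 within the brighter set (adjusted p = 0.00507).

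Several genes that infection had raised were lower after pretreatment. Ndrg1 had a log2 difference of -1.40 ± 0.19 (adjusted p = 0.0204), Mmp3 of -1.26 ± 0.18 (adjusted p = 0.0234), Cxcl2 of -1.23 ± 0.22 (adjusted p = 0.0411), Mt2 of -1.18 ± 0.18 (adjusted p = 0.0255) and Timp1 of -1.07 ± 0.18 (adjusted p = 0.0364). Glyat, an acyltransferase, was lower at -1.18 ± 0.12 and the nucleolar protein Ccdc86 at -1.04 ± 0.11 (adjusted p = 0.00741 for both). Septin11 and the proline synthesis enzyme Aldh18a1 had differences of -1.42 and -1.20. The tRNA methyltransferase subunit Trmt61a was lower as well, at -1.10, though its change of 0.48 in PA against control was not called (adjusted p = 0.14). All 15 named falls kept a negative difference but lost their call in the values as deposited and with a common median; for Ndrg1 the difference as deposited was -1.20 (adjusted p = 0.297) and for Cxcl2 -1.08 (adjusted p = 0.0742). Of the 15, 14 were called within the brighter set, and 2 (Glyat and Ccdc86) kept their call without each array in turn. Without flagellin + PA 1 the adjusted p was 0.0909 for Ndrg1, 0.101 for Mmp3, 0.155 for Septin11, 0.0809 for Aldh18a1 and 0.104 for Trmt61a. Without PA 2 it was 0.107 for Mt2 and 0.135 for Timp1, and without flagellin + PA 2 it was 0.147 for Cxcl2.

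Further lists passed as lower after pretreatment, none of them with an estimated correlation. Of 44 genes of matrix proteases and wound response 3 were lower, as many as adjusted over the list alone (adjusted p = 8.98e-07, and adjusted p = 0.398 with an estimated correlation), with a median of -0.22 that was -0.06 within the brighter set. Of 34 antioxidant and metallothionein genes 2 were lower, Mt2 and Gstm1, and 4 adjusted over the list alone (adjusted p = 0.00207, and adjusted p = 0.103 with an estimated correlation). Of 26 chemokines 1 was lower, and 4 adjusted over the list alone (adjusted p = 0.0254, and adjusted p = 0.398 with an estimated correlation). NF-kB feedback genes had a median of -0.23 (adjusted p = 5.03e-05, and adjusted p = 0.621 with an estimated correlation), with no member called by limma and 8 lower and 1 higher at an unadjusted p below 0.05. The last 2 lists no longer passed within the brighter set (adjusted p = 0.117 and 0.165). Immediate early and heat shock genes had a median of -0.10 (adjusted p = 0.00207, and adjusted p = 0.277 with an estimated correlation), with 4 members lower at an unadjusted p below 0.05 and no call by limma.

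Between the infected groups, 133 genes were higher and 114 lower after pretreatment, with 47 rises and 11 falls of at least 2-fold and 2075 genes at an unadjusted p below 0.05. In the values as deposited 59 were higher and 2 lower, and with a common median 90 and 3. With the block, which for this comparison is the same fit as leaving out PA 1, 247 were higher and 222 lower, of which 125 and 99 were the same genes. Of the 21 rises that the naming rule took, 14 kept their call as deposited, 16 with a common median, 20 with the block and 7 without each array in turn. Without PA 2 there were 8 falls, without flagellin + PA 2 there were 24 rises, and without PA 1, being the blocked fit, there were 247 rises and 222 falls.

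**Figure D3:**
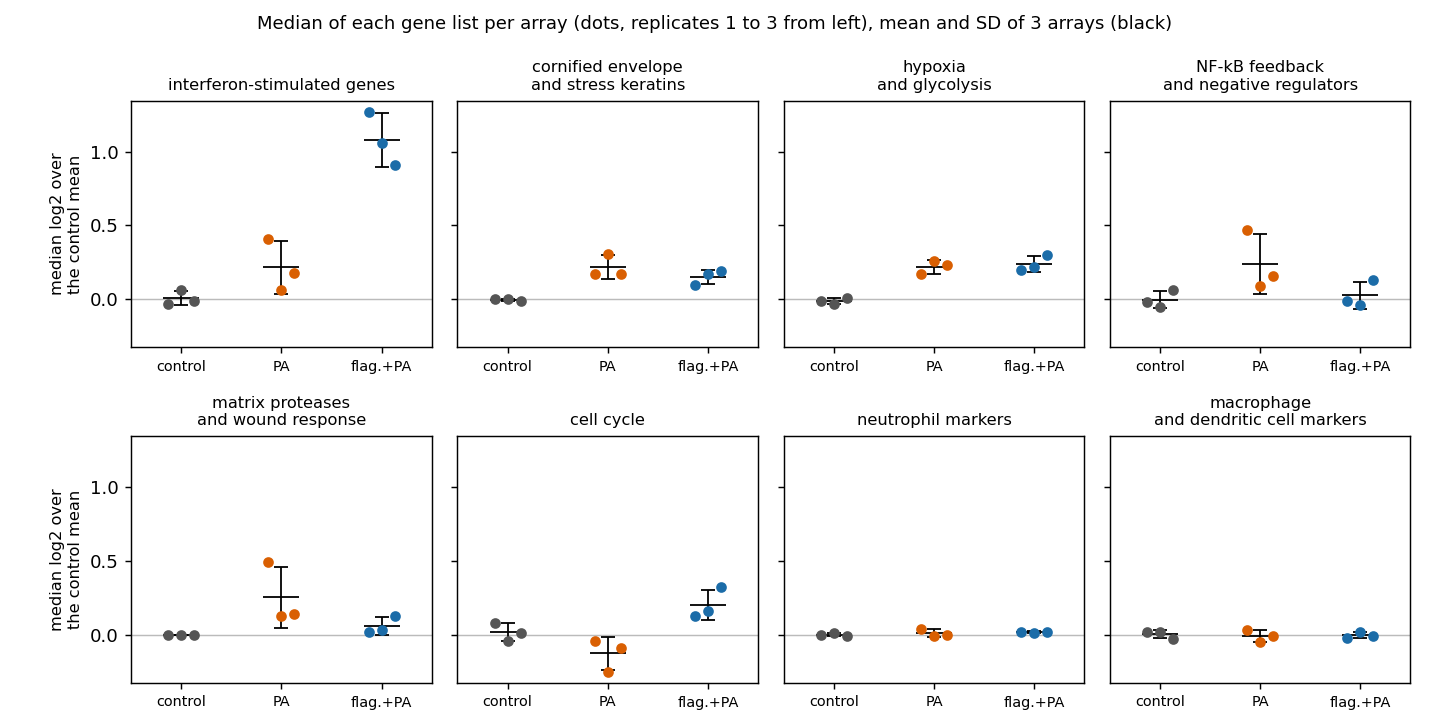
Median log2 difference from the control mean over the measured members of 8 gene lists in each array (dots, 3 per group), with the mean and SD of the group in black. Interferon-stimulated genes stood at 1.27, 1.06 and 0.91 in flagellin + PA, whereas the NF-kB and wound response lists were highest in PA 1.

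Both comparisons of PA share its arrays, so genes high in PA by chance fall in the comparison with flagellin + PA. Of the 416 genes raised by infection, 42 were lower after pretreatment, where independent draws would give 2.5 and simulated data without effects gave 43.1 on average and 59 at most. Of the 1248 genes lowered by infection, 37 were higher after pretreatment, against 8.7 from independent draws and 73 in simulated data. Every gene counted in these simulations was noise, unlike the calls, so they do not decide what the shared arrays alone give. With the brightness set as a block the 2 comparisons share no array, though they share the spread of each gene and the first rests on PA 1 alone. There 60 genes were raised by infection and lower after pretreatment, against 7.7 from independent draws and 20.7 on average and 33 at most in simulated data without effects; 42 were lowered and then higher, against 26.9 on average and 38 at most. Among the 60 were Ndrg1, Mt2, Mmp3, Cxcl2, Timp1 and Aldh18a1. Of 263 genes at least 2-fold higher in that PA comparison, 189 had a negative difference after pretreatment, with a median of -0.26, while 48.9% of all genes did. Of 105 genes at least 2-fold lower, 83 had a positive one.

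A smaller set rose under infection and rose further after pretreatment. It held 10 genes, against 2.9 from independent draws and at most 3 in simulated data, and with the block 37, where simulated data gave 22.4 on average and 35 at most. The 10 were Ifitm2, Ccng2, B2m, Klk10, Klk8, S100a9, Shisa5, Ogfr, Adamtsl4 and Otud5, of which all but S100a9 were outside the naming rule and chosen after their values were seen. Their number was 2 without control 1 and 23 without PA 1, and that of the 42 was 3 without PA 2 and 122 without PA 1; the 37 genes lowered and then higher were 2 without PA 2 and 92 without PA 1.

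Markers of other cells gave no call as lists in any of the 3 comparisons with all arrays. The neutrophil list, with 1 of 35 members higher in PA, gave adjusted p-values of 0.196, 0.33 and 0.759 in the order PA against control, flagellin + PA against control, and flagellin + PA against PA; within the dimmer set, where PA is PA 1 alone, it passed in PA against control, with 3 members higher and a median of 0.04 (adjusted p = 0.0296, and adjusted p = 0.133 with an estimated correlation). With the block it also passed in flagellin + PA against control, at a median of 0.04 (adjusted p = 0.0213, and adjusted p = 0.106 with an estimated correlation), as did macrophage and dendritic cell markers, at a median of 0.07 and with no member called (adjusted p = 0.00549, and adjusted p = 0.133 with an estimated correlation). The called neutrophil marker in PA was the stefin Stfa2, up by 1.85 ± 0.33 (adjusted p = 0.0124). In flagellin + PA against control 2 markers were called, Stfa2, up by 1.27 (adjusted p = 0.0491), and the chemokine receptor-like Ccrl2, up at least 1.72-fold (adjusted p = 0.0185), and both calls were lost with the block (adjusted p = 0.084 and 0.141); Ccrl2 differed from PA by 0.81 (adjusted p = 0.087). S100a8 and S100a9 are abundant in neutrophils as well as in stressed epithelium. In the same order the adjusted p-values were 0.973, 0.571 and 0.564 for macrophage and dendritic cell markers, 0.855, 0.83 and 0.669 for lymphocyte and NK cell markers, and 0.203, 0.571 and 0.669 for keratocyte and fibroblast markers. They were 0.471, 0.471 and 0.759 for conjunctival and goblet cell markers, 0.376, 0.571 and 0.669 for vascular and lens or retinal markers, and 0.747, 0.609 and 0.669 for erythroid markers. Their medians lay between -0.06 and 0.01. Few of these markers could be seen: 12 of 35 neutrophil, 11 of 35 macrophage and dendritic cell, and 7 of 24 lymphocyte and NK cell markers were above background in at least 3 arrays.

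Other lists also stayed short of a call, again in that order. The adjusted p-values were 0.583, 0.813 and 0.564 for oxidative phosphorylation, 0.348, 0.602 and 0.669 for cytosolic ribosomal proteins, and 0.855, 0.609 and 0.461 for the circadian clock. They were 0.51, 0.855 and 0.292 for junctions and surface mucins, 0.614, 0.571 and 0.759 for complement and acute phase, 0.51, 0.83 and 0.564 for eicosanoid and lipid mediator genes, and 0.376, 0.571 and 0.759 for sex-linked genes. The sex-linked list pools Xist with Y-linked genes such as Eif2s3y, which moved in opposite directions. Their changes cancel in a test of direction, so the missing call does not mean that the groups were alike in sex-linked transcripts. With the block, oxidative phosphorylation was lower against control in both infected groups (median -0.19 and -0.26, adjusted p = 0.000435 and 2.05e-05, and adjusted p = 0.133 and 0.087 with an estimated correlation). In the values as deposited its median in flagellin + PA against control was 0.42, or 0.33 above that of all genes. Complement and acute phase passed as higher with the block in PA and in flagellin + PA against control (adjusted p = 0.0493 and 0.00549, and adjusted p = 0.133 and 0.087 with an estimated correlation), and cytosolic ribosomal proteins as lower in flagellin + PA against control and against PA (adjusted p = 0.00721 and 0.0135, and adjusted p = 0.314 and 0.401). Others that passed only with the block were immediate early and heat shock genes as higher in PA against control (adjusted p = 0.00226, and adjusted p = 0.133 with an estimated correlation) and hypoxia and glycolysis as lower in flagellin + PA against PA (adjusted p = 0.0362, and adjusted p = 0.401). In flagellin + PA against control these were NF-kB feedback, wound response, cell death genes and chemokines, all as higher, at blocked medians of 0.47, 0.27, 0.14 and 0. These values carry over how PA 1 differed from PA 2 and PA 3, because the block links the groups only through PA. Over the control mean, the NF-kB medians of the 3 flagellin + PA arrays were -0.01, -0.04 and 0.13, against 0.47 in PA 1. Those of wound response were 0.02, 0.03 and 0.13, against 0.49 in PA 1.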

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

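The tests of PA 1, of the excess of falls and of leukocytes, and every value with the brightness set as a block, were chosen only after the result was seen; the tests of one array, of normalization and of other splits were planned.

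Probes without a single gene name, which no comparison used, also carried signal above the controls. Of 10396 such probes, limma called 82 higher in PA against control, 88 in flagellin + PA against control and 6 in flagellin + PA against PA, beside 138, 162 and 8 lower. The probe ILMN_1257771 rose by 2.90 ± 0.17 in PA (SE, adjusted p = 0.000384) and by 4.02 ± 0.17 in flagellin + PA (adjusted p = 8.41e-05), and ILMN_2534207 was higher by 1.60 ± 0.17 in flagellin + PA than in PA (adjusted p = 0.012).

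PA 1 lay apart from PA 2 and PA 3, with 1271 genes different between them in the blocked limma fit, 672 higher and 599 lower in PA 2 and PA 3. Uninfected cells in the sample or a control array under its label are argued against: of the 167 genes at least 2-fold higher in flagellin + PA against control, 43.7% were higher in PA 1 than in both other PA arrays and 50.3% lower than in both, where added control RNA would lower nearly all. Low signal is argued against as the whole cause, since in the 1906 brightest genes PA 1 differed from the others with an SD 3.35 times that between PA 2 and PA 3 (0.45 against 0.13). A difference in labelling or hybridization that acts on single probes may contribute: across 1160 genes, genes not being independent replicates, the difference of PA 1 from PA 2 and PA 3 correlated between the 2 brightest probes of a gene at r = 0.46, against 0.66 for flagellin + PA 3 minus the other 2 arrays of its group, the comparison the prediction named, 0.67 for PA 2 and PA 3 minus the controls, 0.84 for PA 1 minus the controls and 0.89 for flagellin + PA minus PA 2 and PA 3. The cytokine Il24 and the protease Mmp10, higher in PA 1 by 2.81 and 2.64 and chosen after their values were seen, leave a stronger infection in that sample open as well, and no biological explanation was tested. Among the 672 genes lower in PA 1, Arpc2 and Eif3a, chosen in the same way, followed the brightness sets. Arpc2 stood at 10.67 in PA 1, 11.05 to 11.07 in controls and 12.26 to 12.67 in the other infected arrays. Eif3a stood at 8.01, 8.33 to 8.46 and 9.36 to 10.14 in the same order.

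Falls outnumbered rises 3 to 1 in PA against control, at 1248 against 416. Quantile normalization of arrays that differ in brightness is a candidate explanation: the share of falls among calls was 75% after it, 28.2% in the values as deposited and 50.5% with a common median, the higher of the last 2. A true excess of falls after infection was not separable from this, because the brightness sets partly follow the groups. With the set as a block, which compares PA 1 with the controls, 936 genes fell and 661 rose.

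Interferon-stimulated genes were higher in flagellin + PA than in PA, with a median difference of 0.81. Leukocytes in the pretreated samples are argued against as its source only as far as their markers could be seen. The 30 leukocyte markers above background, none of them on the interferon list, had a median difference of 0.00 and an upper quartile of 0.08. Most markers were at background: 12 of 35 neutrophil, 11 of 35 macrophage and dendritic cell, and 7 of 24 lymphocyte and NK cell markers were above it. The test therefore cannot exclude leukocytes. Markers of macrophages and dendritic cells did pass as a list within the brighter set (adjusted p = 0.0362, and adjusted p = 0.392 with an estimated correlation). Their median of 0.04 says little, because most of the 35 lay at background. The 1 called with all arrays, Ctss, was at background in all 3 PA arrays, so its difference of 0.40 (adjusted p = 0.0395) is understated. A single array and the normalization are argued against too, since the median was at least 0.67 without each array in turn, and at least 0.90 in the values as deposited and with a common median. A lasting or primed interferon response after flagellin is a hypothesis that was not tested. A response to flagellin alone remains open without that group, and so do leukocytes whose markers lay at background.

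Each pair of groups allows 10 splits of its 6 arrays, too few for a share under 0.05. In PA against control the real split gave 416 rises, 1248 falls and 232 changes of at least 2-fold, and the highest of the other 9 splits gave 0 of each by limma, with 343 to 2420 genes at an unadjusted p below 0.05. In flagellin + PA against control the real split gave 536, 1239 and 244, and the highest other gave 50, 50 and 26; it set control 2, flagellin + PA 1 and flagellin + PA 2 against the rest. In flagellin + PA against PA the real split gave 133, 114 and 58, and the highest other gave 0 of each, with 294 to 1720 genes at an unadjusted p below 0.05. In each case 1 of the 10 splits, the real one, gave a count as large.

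For the overlaps, 100 assignments of the 9 arrays to 3 groups of 3 were drawn, the real one included. An overlap as large as the 42 genes raised by infection and lower after pretreatment came in 2 of them, as large as the 37 lowered and then higher in 2, and as large as the 10 that rose in both comparisons in 1. An overlap needs calls in both comparisons, and most other splits above gave none, so these counts do not test the overlaps apart from the number of calls. Simulated data without effects, with shared PA arrays and the same numbers of genes, gave 43.1, 73 and 0.6 on average in the same order. The first 2 overlaps were no larger than that, while the 10 were more than the 3 that simulations gave at most. Every gene counted in the simulations was noise, unlike calls that passed an adjusted p, so they do not decide what the shared arrays alone give. The highest other assignment gave 599, 121 and 0; it kept the 3 controls together against mixed infected arrays, which points to the distance of the controls from all infected arrays as a structure of the samples.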

How the results depend on the processing

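The normexp correction, the joint omission of arrays and the brightness block were chosen only after the results were seen; the other alternatives were planned. Counts below are higher / lower / at least 2-fold where 3 are given, and the overlaps are, in order, raised by infection and lower after pretreatment, raised and higher, lowered and higher; where no cause is named, the cause was not tested. Of 219 calls of named genes, 119 held in the values as deposited, 117 with a common median, 193 with a floor, 189 with probes averaged, 174 with the compared groups only, 170 with the replicate block, 201 with trend and robust spread, 218 with array weights, 199 after normexp, 50 without controls 1 and 2, 215 without PA 1 and flagellin + PA 3, and 134 with the brightness block. Without 1 array, 133 (control 1) to 215 (PA 1) held. Probes at background limit what dim genes can show, and Krt12 and Krt16 stood near the top of the scale. Of 9 pairs of arrays with the same replicate number 3 had deviations correlated above 0.1, so the data give the replicate block little basis. The planned floor at the smallest positive value and the addition of 50 units were not run, because the values were already logarithms.

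As deposited, PA against control gave 199 higher and 78 lower, flagellin + PA against control 53 lower, flagellin + PA against PA 59 higher and 2 lower, and overlaps 1 and 3 were 2 and 2. Signs turned for Ndufb8 in PA against control (0.044) and, in flagellin + PA against control, for Ndufv1 (0.087), Atp5o (0.246), Ndufa10 (0.019), Evpl (0.072), Rpl35 (0.332) and the mean of the oxidative phosphorylation list (0.505). With a common median, PA against control gave 145 higher, 148 lower and 125 at least 2-fold, flagellin + PA against control 311 higher and 85 lower, flagellin + PA against PA 3 lower, and overlaps 1 and 3 were 2 and 7. Signs turned in flagellin + PA against control for Ndufv1 (0.025), Atp5o (0.185), Evpl (0.01), Rpl35 (0.27) and oxidative phosphorylation (0.444).

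With the floor, flagellin + PA against PA gave 80 higher and 68 lower and overlaps of 27, 6 and 22. With probes averaged, 131 and 159 genes were at least 2-fold changed in PA and in flagellin + PA against control, and Ndufa5 (0.063, PA) and Atp5o (0.025, flagellin + PA) turned sign. With the compared groups only, which leaves fewer arrays for the spread, flagellin + PA against control gave 971 higher, flagellin + PA against PA 8 / 2 / 8, and overlaps 1, 0 and 1. With the replicate block, flagellin + PA against PA gave 32 / 12 / 20 and overlaps 7, 2 and 6. With trend and robust spread overlap 3 was 12. Array weights, which gave PA 1 the lowest weight (0.276), gave 1108 higher and 2151 lower in PA against control, 1145 and 2150 in flagellin + PA against control, 385 and 364 in flagellin + PA against PA, and overlaps 151, 35 and 150.

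Normexp, which widens folds by taking off background, gave 586, 624 and 117 genes at least 2-fold changed in the 3 comparisons, 69 lower in flagellin + PA against PA and 10 in overlap 3. Without controls 1 and 2, which leaves 1 control that is assumed to vary like the other groups, the counts were 55 / 243 / 107 for PA against control, 70 / 236 / 103 for flagellin + PA against control, and 8 / 2 / 8 for flagellin + PA against PA, with overlaps 0, 1 and 0. Without PA 1 and flagellin + PA 3 they were 1430 / 2328 / 386, then 1288 higher and 2188 lower, then 362 / 408 / 122, with overlaps 256, 51 and 154. The brightness block gave 661 higher and 368 at least 2-fold in PA against control, 332 higher and 371 lower in flagellin + PA against control, 247 higher and 222 lower in flagellin + PA against PA, and 37 in overlap 2; in flagellin + PA against control Cxcl10 (0.551) and the mean of cytosolic ribosomal proteins (-0.17) turned sign.

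With each array left out in turn, PA against control ranged from 167 to 1109 higher, 596 to 1861 lower and 146 to 366 at least 2-fold, all lowest without control 1 and highest without PA 1. Flagellin + PA against control ranged from 240 to 1146, 629 to 1927 and 166 to 296, with the same arrays. Flagellin + PA against PA ranged from 24 (without flagellin + PA 2) to 247 higher, 8 (PA 2) to 222 lower, both highest without PA 1, and 19 (flagellin + PA 2) to 83 (flagellin + PA 3) at least 2-fold. The overlaps ranged from 3 to 122, 2 to 23 and 2 to 92, lowest without PA 2, control 1 and PA 2, and all highest without PA 1.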

Other observations

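The 3 gene groups described first, and their tests, were chosen only after the result was seen. The omission of control pairs was also chosen after the split of the controls was seen, with its prediction written before its value.

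Genes of ribosome biogenesis, the nucleolar factors that build ribosomes, were lower after pretreatment in infected cells. The group was written out after several members appeared among the largest differences between flagellin + PA and PA. Of 87 measured members 12 were higher and 1 lower in PA against control, with a median log2 change of 0.22. Between flagellin + PA and PA 16 were lower, 80 had a negative difference and the median was -0.32. Genes of amino acid synthesis and tRNA charging went the same way: of 39 members 8 rose and 2 fell in PA against control, with a median of 0.22, and 4 were lower in flagellin + PA than in PA, with a median of -0.36 and 32 negative differences. The hypothesis was that each group moved together beyond the members seen first. Without those, camera with an estimated correlation gave a p of 0.00452 for ribosome biogenesis over 79 members and 0.00359 for amino acid synthesis and tRNA charging over 36, each with an adjusted p of 0.0203 over 18 such tests. These p-values describe a lower level of both groups in these arrays. They are no independent test, because the groups were written after their members led this same comparison. The adjustment over 18 tests does not cover the search that picked the groups. In flagellin + PA against control 8 genes of ribosome biogenesis were lower and 1 higher, and 58 of 87 had a negative difference, with a median of -0.08 (p = 0.383 with an estimated correlation); with the brightness block 5 were lower and 65 negative, with a median of -0.15 (p = 0.23). The medians over control were 0.12, 0.29 and 0.17 for ribosome biogenesis in the PA arrays and -0.18, -0.08 and -0.06 in flagellin + PA. Within the brighter set, 23 and 13 members of the 2 groups were lower in flagellin + PA, with medians of -0.37 and -0.32 (p = 0.00726 and 0.00657 with an estimated correlation, all members included). As deposited the medians were -0.22 and -0.22. The rise under infection alone was less certain: in PA against control the estimated-correlation p was 0.0267 and 0.00858 (adjusted p = 0.0437 and 0.0212 over 18 tests), without the members seen first 0.0374 and 0.0135 (adjusted p = 0.0561 and 0.0243), and 0.19 and 0.0304 with the brightness block.

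Genes of MHC class I presentation, which display peptides to T cells and are known to respond to interferons, had 1 of 27 members called higher under infection alone, with a median of 0.10. Of the 27, 4 are also on the list of interferon-stimulated genes. After flagellin and infection 10 rose against control, with a median of 0.46 (p = 0.00938 with an estimated correlation, adjusted p = 0.0212 over 18 tests), and 6 were higher than in PA, with a median of 0.33 (p = 0.00834, adjusted p = 0.0212). The median over control was 0.67, 0.50 and 0.16 in the 3 flagellin + PA arrays. Within the brighter set 12 members were called higher than in PA, with a median of 0.39.

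The controls were not alike in sex-linked transcripts. Xist, expressed from the inactive X chromosome, stood at 6.62 and 6.69 in controls 1 and 2 and at 9.94 to 11.38 in the other 7 arrays, and the Y-linked Eif2s3y at 9.48 and 9.09 in those controls and at 6.54 to 6.74 elsewhere. Whether this split could account for the calls against control was tested by leaving out pairs of controls. Without controls 1 and 2 limma called 298 genes in PA against control, without controls 1 and 3 it called 15 and without controls 2 and 3 it called 368. With 1 control left, the other pairs alone ranged from 15 to 368, so the bound set in advance, a part of their lowest count, could hardly fail and the test decides nothing. With control 3 as the only control, which has the pattern of the infected arrays, none of the 219 calls of named genes turned sign. That outcome was fixed in advance, because the values of the compared groups did not overlap for any named call. It therefore says nothing about the split. The 219 calls include 21 rises and 15 falls of flagellin + PA against PA, which uses no control, so calls lost in that comparison do not bear on the split either. With 1 control, fewer arrays and a difference in sex between animals are not separable as reasons for a loss, and the latter stays open.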
